A study of Cordyceps militaris with 6 samples.

How the data were processed

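Poly(A)-selected RNA was sequenced from mycelium of the YCC strain of Cordyceps militaris, an ascomycete fungus grown for its fruiting bodies and for cordycepin (3'-deoxyadenosine). Per the labels' protocols, hyphae were grown for 72 h in shaken liquid medium in the dark, RNA was extracted with a column kit and treated with DNase, and complementary DNA fragments of one size class were selected on a gel. The labels give 6 libraries, 1 for each of passages 1 to 6 of a subculture series. No passage had a replicate library, so no pair of passages could be tested against replicate spread, and the 6 libraries come from one lineage, so neighbouring passages may depend on each other.

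The authors deposited 1 table of gene expression for all libraries. Its expected counts per gene, per the file headers and values, are estimated reads that were not normalised. As written, with no tolerance, 36 to 50 of 10385 genes per library had values that were not whole. Its FPKM values, per the file headers, are fragments per kilobase scaled to library size, given to 2 decimals. Per the submitters' processing notes, FastQC, Bowtie, TopHat2, Cufflinks and edgeR were used; their versions, their order and the counting settings, strand included, are not given in the sources used here. Sequence names in the deposited tables are RefSeq scaffolds of the C. militaris CM01 genome. Without stated strand use, reads of overlapping and antisense genes could not be told apart, and values of gene families with near-identical copies are uncertain.

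Per the file headers, the authors also deposited 5 tables that set each later passage against passage 1, with a log2 ratio of FPKM and a p-value and FDR per gene. Every gene in them had an FDR under 0.05 and at least a 2-fold difference. These came from 1 library against 1 library, so the p-values speak of those libraries and not of the passages. The authors' table of single nucleotide variants and indels holds a quality score per site, which the file headers name and whose minimum was 30.02. Other deposited values in it are genotype codes and pairs of reference and alternative read numbers per library; the variant caller is not given in the sources used here. The deposited table of RNA editing events gives a frequency per event as a fraction of reads, from 0.1 to 0.9, per the file headers and values. Its title says that the events were based on single nucleotide variants, and the rule for calling them is not given in the sources used here. The authors' junction tables give raw counts of reads per splice junction, a junction name and a class word. Deposited lists of extended gene models, of genes outside the reference annotation and of Pearson correlations between libraries completed the set, all with other units such as base pairs or correlation coefficients. The expression table, the variant table and the junction tables were read by column names that match the labels. A further 50 columns of per-sample values were not used.

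Gene names came from the product text of the deposited table. The 9651 locus tags of reference genes were all found in a RefSeq gene table of assembly CmilitarisCM01_v01, which was used for names and gene order only. Of the 10385 genes, 734 were outside the reference annotation, 8857 had a named product and 639 had no count in any library. Total counts per library ranged from 9740171 to 13813999.

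Expected counts were rounded to whole numbers. The design, the gene lists, the rule for named genes and the alternatives not marked as later choices were chosen before the data were examined. The design named limma on log2(FPKM + 1) for a table of FPKM alone and edgeR for counts; since the deposited counts were whole for nearly all genes, edgeR was used. Library sizes were scaled by TMM. FPKM printed beside ratios are as deposited and not scaled by TMM, so they need not match the ratios. Differences between a later passage and passage 1 were computed as log2 CPM (counts per library size scaled by TMM) with a prior count of 1, over the 8483 genes with a mean of at least 1 FPKM, and genes at least 2-fold apart were counted in each direction. With 1 library per passage these counts have no test. Intervals printed for log2 ratios, shares and read fractions are 95% intervals of counting error (binomial on the pair of counts for ratios, Wilson for shares); they leave out biological and library variation, and amplified reads are not independent molecules. Where a gene had 0 counts in passage 1, its fold was computed against a floor of 3 counts in that library.

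A trend over passages was tested with edgeR's quasi-likelihood test, with passage number as a numeric term, over the 8758 genes that passed edgeR's expression filter, two-sided, with Benjamini-Hochberg adjustment at 0.05. In simulated counts for 8758 genes it recovered 85 of 100 genes with a slope of 0.5 log2 per passage and 98 of 100 with a slope of 1, with 8 false calls. After the expression values were seen, passage 1 was also compared with the 5 later passages in one edgeR fit, which assumes that the lone library varies like the other 5. In simulated counts for 8758 genes this comparison recovered 3 of 100 genes with a log2 difference of 1 and 57 of 100 with a difference of 2, with 6 false calls. Both simulations took their spread from the fit on passage number, in which a difference of passage 1 alone counts as spread. They changed only genes above a minimum expression. The recovery in the second simulation is therefore not the power of the comparison that was used. In the first, libraries were drawn independently, without dependence between neighbouring passages. It also changed 100 genes of each size at once, which eases the adjustment. Its recovery is therefore not the power of the trend test on these libraries. A passage is confounded with its library in both tests.

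A trend of each library with gene length was removed in a further setting chosen after the data were seen: the log2 deviation of each gene from its mean was smoothed against the length implied by its counts and FPKM (lowess), and the smoothed value entered the edgeR offset. Lengths were available for all 8483 genes with at least 1 FPKM. A second setting chosen then thinned all libraries at random to the smallest total. FPKM as deposited, limma on log2(FPKM + 1) and edgeR without an expression filter were also taken up as alternatives after the data were seen.

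Gene lists were defined by keywords in the product text, 25 in all: the 4 genes of the cordycepin cluster, purine metabolism, hydrophobins, conidiation, fruiting body and mating, photoreceptors and carotenoids, polyketide and peptide synthases, cytochrome P450, antioxidant enzymes, heat shock proteins and chaperones, glycoside hydrolases, cell wall synthesis and structure, secreted proteases, major facilitator (MFS) transporters, ribosomal proteins without a mitochondrial label, mitochondrial ribosome, oxidative phosphorylation, glycolysis and tricarboxylic acid cycle, proteasome, autophagy, DNA replication and repair, histones and chromatin, signalling kinases and G proteins, transposons, and zinc cluster transcription factors. The keyword of the signalling list was corrected after its matches, but not its values, had been seen. Keyword lists hold some false matches. Each list with at least 4 tested genes was tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists. For single passages the median of a list was ranked among 10000 random lists of equal size matched on mean expression.

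Genes are named in the text by a rule. For the trend these are the 10 largest slopes in each direction among genes that pass, or, where fewer pass, the 5 smallest p-values, among genes with a named product and at least 5 FPKM in a library. For each passage they are the 4 highest and the 4 lowest ratios among genes with a named product and at least 10 FPKM in 1 of the 2 libraries. For each list they are the 3 members with the largest absolute slope, and all 4 cordycepin genes. For variants, editing and splicing they are the 3 genes with the most sites or events. Genes named outside this rule are marked as such.

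Variant sites were counted per library where the genotype code held an alternative allele, with a 0|1 code counted as a mixed call. After the mixed calls had been seen, sites with at least 20 reads in all 6 libraries were called mixed where the alternative share lay between 10% and 90% in at least 4 libraries. Runs of 100 kb windows with at least 10 mixed sites, and at least 100 mixed sites in all, formed a stretch; the minimum of 100 was set after a group of 23 sites had been seen. The second allele of a mixed site was the one passage 1 lacked, taken at sites where passage 1 had at least 95% or at most 5% of its reads with the alternative base. Editing events were matched by position to the variant table. Junctions of the 6 classes IR, ES, AFS, ALS and alternative 3' and 5' splice sites, as the authors' files name them, were counted as alternative; known, intergenic and other junctions were not. Relations across the 6 libraries were tested by exact permutation of their order, two-sided, and 10 such relations were adjusted together. The Pearson r was also computed without the 2 libraries farthest from the median of the value set against, such as passage number or total counts.

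Alternatives (prior count, filter, scaling, tool, control library, left-out libraries, depth minimum, types of site) were computed where they applied to the counts of genes, gene lists, variant sites, editing events, junctions and correlations between libraries; none were computed for the shares of the second allele, the relation of MAT1-1-1 or the fit of expression to those shares, other than those printed with them. Computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.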

Results

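The series follows the YCC strain of Cordyceps militaris through serial subculture, with 1 mycelium library from each of passages 1 to 6 after 72 h in the dark. Its stated purpose is to see how transcriptomes diverge as a strain degenerates, the loss of fruiting that subculture can bring. Gene expression, sequence variants, RNA editing events and splice junctions were read from the same 6 libraries. Total expected counts were 9740171 in passage 1, 13813999 in passage 2, 10930180 in passage 3, 12915930 in passage 4, 12286766 in passage 5 and 13609435 in passage 6. Between 9254 and 9449 genes had a count in a library. The gene with the most counts, CCM_04804, took 1.65% to 3.06% of a library. No passage had a replicate, so differences between single libraries are given as values without a test.

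The passage 1 library stood apart from the other 5. Over log2(FPKM + 1), its Pearson correlations with the later passages ran from 0.943 to 0.961, while those among passages 2 to 6 ran from 0.972 to 0.992. With untransformed FPKM, as in the authors' deposited table of correlations, passage 1 had values from 0.862 to 0.911. These are correlations across genes, which are not independent replicates. In a principal component analysis the first component held 57.0% of the variance, with passage 1 at -68.0 and the others between -2.46 and 28.5. The next component held 20.2% and placed passage 6 at 38.7. In passage 1, 807 of 8483 genes differed at least 2-fold from each of the other 5 libraries (415 higher, 392 lower), against 7 to 81 such genes in any later passage. Passage 1 also differed from the rest by gene length. Across 8483 genes its log2 deviation from the mean of the other 5 libraries rank-correlated with gene length at rho 0.391, against -0.133 to -0.302 in the later passages. The mean set against a later passage includes passage 1, which by itself makes rho negative. The negative values therefore need not be a length trend of each later library. Passage 1 has the same weight in each of these means. Still, rho was -0.302 in passage 6, against -0.133 to -0.183 in passages 2 to 5. Passage 6 thus differed by gene length from the other later passages. Genes of at most 0.891 kb had a median deviation of -0.44 in passage 1, and genes of at least 1.98 kb one of 0.38.

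**Figure D1:**
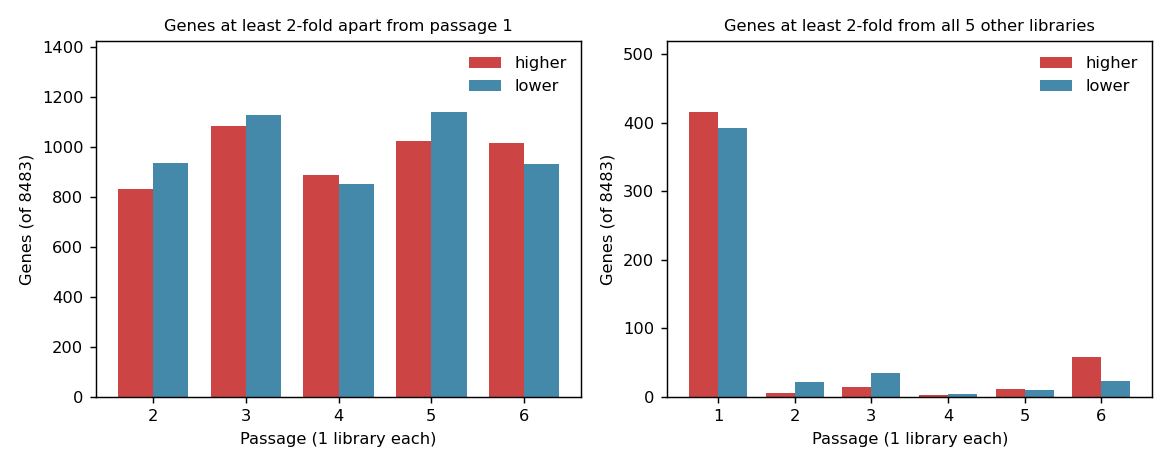
Left, genes at least 2-fold higher or lower in each of passages 2 to 6 than in passage 1; right, genes at least 2-fold higher or lower in 1 library than in each of the other 5. Bars are numbers of genes of 8483, with 1 library per passage and no error; in the right panel passage 1 has 807 genes and no other passage more than 81.

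Each later passage was set against passage 1 to see which genes accompany subculture. Among genes with a named product and at least 10 FPKM in 1 of the 2 libraries, the highest ratios in passage 2 were those of a protease, a cell wall protein and a transporter. The subtilisin TCONS_00010916 was 15.4-fold higher than in passage 1, a galactomannoprotein of the cell wall (CCM_06851) 12.3-fold, and the siderophore iron transporter mirB (CCM_08808) 10.3-fold, from 16.8 to 202.1 FPKM. The trypsin-like protease CCM_03489 had a log2 ratio of 3.27 (interval 2.98 to 3.59). Among the lowest were the ubiquitin ligase gene Hul4 (CCM_00412), with 1 count in passage 2 (log2 ratio -8.36, interval -14.75 to -6.96), and the RTA1-like gene CCM_07219, also with 1 count (-7.44, interval -13.84 to -6.03). The MFS transporter CCM_03001 had a log2 ratio of -5.87, and the phase-specific gene CCM_09641 went from 368.8 to 7.53 FPKM. In all, 1766 of 8483 genes were at least 2-fold apart, 831 higher and 935 lower.

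In passage 3, the MFS transporter CCM_08483 had the highest ratio, with 2 counts in passage 1 and 36.4 FPKM in passage 3 (log2 7.41, interval 5.98 to 10.89). The galactomannoproteins CCM_00410 and CCM_00403 had no count in passage 1 and were at least 20.5-fold and at least 15.6-fold higher in passage 3. Their neighbour CCM_00411 had a log2 ratio of 5.76 (interval 4.49 to 8.34). CCM_00412 was again low (-6.61, interval -8.49 to -5.62), as were CCM_07219 with 3 counts (-6.28, interval -8.96 to -5.11) and the MFS transporter CCM_08259, which was 76.9-fold lower than in passage 1. CCM_09641 had a log2 ratio of -6.05. Between passages 3 and 1, 2209 genes were at least 2-fold apart, 1083 higher and 1126 lower.

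In passage 4, the highest ratios were those of CCM_08483 (log2 6.51, interval 5.07 to 9.98), CCM_03489 (35.2-fold), the immunization antigen CCM_00147 (log2 4.88) and the LCCL domain gene CCM_09343 (log2 4.42). The chitinase ChiA1 (CCM_06535) went from 1493 FPKM in passage 1 to 109.1 FPKM, a log2 ratio of -4.06 (interval -4.11 to -4.01). The MFS transporter CCM_08259 was 103.3-fold lower, a phospholipase A2 (CCM_07919) had a log2 ratio of -4.90 and CCM_03001 one of -4.69. At least 2-fold apart were 1741 genes, 889 higher and 852 lower.

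In passage 5, CCM_03489 reached 1006 FPKM, 67.0-fold above passage 1. The enterotoxin A chain gene CCM_08244 had no count in passage 1 and was at least 37.5-fold higher, CCM_08483 had a log2 ratio of 6.11 (interval 4.66 to 9.59) and CCM_00147 one of 5.29. The lowest were CCM_08259 (log2 -6.82), the cellobiose dehydrogenase CCM_06091 (-5.91), CCM_07919 (-5.78) and CCM_09641 (-5.68). Against passage 1, 2160 genes were at least 2-fold apart, 1022 higher and 1138 lower.

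In passage 6, a metalloprotease (CCM_07917) and CCM_03489 had log2 ratios of 4.85 and 3.99. Glucose oxidase CCM_02694 went from 0.32 FPKM, or 3 counts, to 12.9 FPKM (log2 4.79, interval 3.50 to 7.37), and the CipC gene CCM_08684 had a log2 ratio of 4.06. CCM_08259 had 2 counts in passage 6 (log2 -7.69, interval -11.38 to -6.47), CCM_03001 a ratio of -5.0, CCM_07919 of -4.20 and the ABC transporter CCM_08739 of -4.19. Of 8483 genes, 1947 were at least 2-fold apart, 1015 higher and 932 lower. The split by direction depended on scaling in all 5 comparisons: 47.1%, 49.0%, 51.1%, 47.3% and 52.1% of these genes were higher with TMM-scaled counts in passages 2 to 6, and 64.2%, 68.5%, 73.5%, 61.9% and 72.4% with FPKM as deposited, a scaling taken up after the data were seen, whose median over genes lay 0.19 to 0.27 log2 above passage 1. Against the preceding passage in place of passage 1, 402, 456, 382 and 792 genes were at least 2-fold apart in passages 3, 4, 5 and 6.

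Passage 1 was then compared with the 5 later passages together, a comparison chosen after the libraries had been seen. The chitinase ChiA1 (CCM_06535) fell by 3.59 log2 (SE 0.341, adjusted p = 0.00339, edgeR with Benjamini-Hochberg adjustment), and the cell wall protein SED1 (CCM_08945) fell by 3.74 log2 (SE 0.353, adjusted p = 0.00339). VeA (CCM_04531), a velvet regulator of development in filamentous fungi, fell by 1.55 log2 (SE 0.164, adjusted p = 0.00345), and AbaA (CCM_05444), a regulator of conidiophore development, fell by 2.21 log2 (SE 0.486, adjusted p = 0.0204), a call lost with the length trend removed (-1.82, adjusted p = 0.0541). The subtilisin TCONS_00010916 rose by 4.15 log2 (SE 0.37, adjusted p = 0.00319). In all, 2103 of 8758 genes passed, 839 higher and 1264 lower in the later passages, with 3514 genes at an unadjusted p under 0.05. With any other single library set against the remaining 5, no gene passed in edgeR, and 41 to 443 genes had an unadjusted p under 0.05. Passage 1 lies in the group of 5 there and widens its spread, so these fits are no control for the 2103 calls. DESeq2 called 2551 genes for passage 1, and limma on log2(FPKM + 1) called 2586, with 70.4% of them higher against 39.9% in edgeR. The test assumes that the lone library varies like the other 5, and the passage cannot be separated from its library. Without passage 5 the count was 1380, with the trend in gene length removed it was 1457, and 1174 genes were called in the same direction with and without the length trend.

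**Figure D2:**
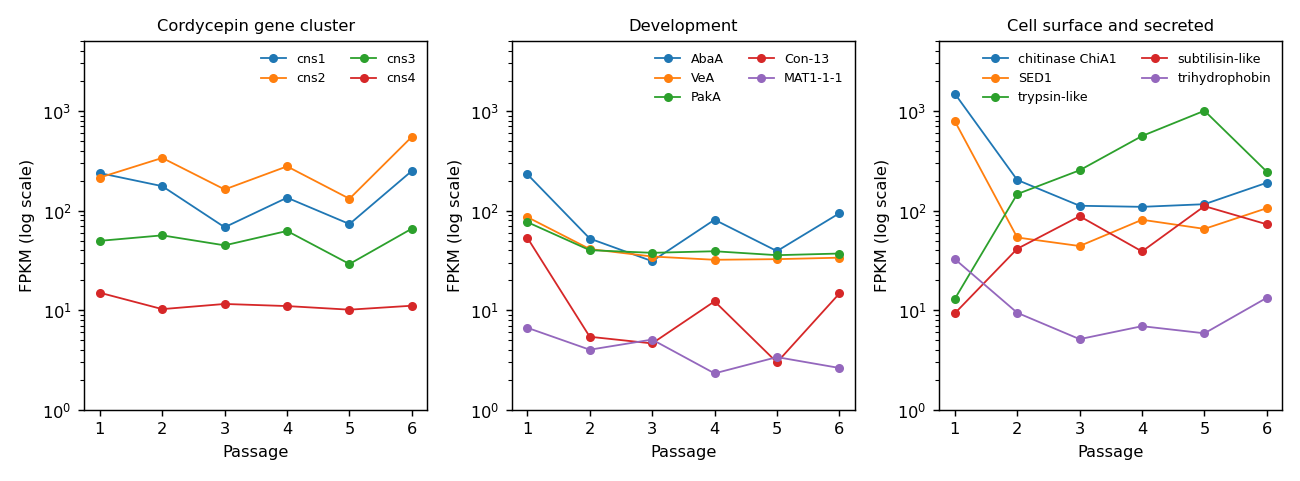
FPKM on a log axis over passages 1 to 6, 1 library each, for the 4 cordycepin cluster genes, 5 genes of development and 5 cell surface or secreted proteins. ChiA1 lies at 1493 FPKM in passage 1 and at 109.1 in passage 4, and the trypsin-like gene CCM_03489 reaches 1006 in passage 5.

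By camera at its preset correlation, the cell wall list moved down against other genes in the later passages (adjusted p = 0.00681, and adjusted p = 0.249 with an estimated correlation). Of its 55 tested genes, 19 fell and 2 rose (23 and 3 adjusted over the list alone), with a median of -0.47 log2 and, opposite in sign, a mean of 0.02. Besides SED1, a GPI-anchored glucanase (CCM_03032) fell by 3.25 log2 (SE 0.456, adjusted p = 0.00555) and a lectin/glucanase-like protein (CCM_08732) fell by 4.23 log2 (SE 0.306, adjusted p = 0.00319). With the length trend removed the list had a median of -0.51 and a camera adjusted p of 0.0116, and an adjusted p of 0.959 with an estimated correlation.

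Of 14 tested genes of fruiting body formation and mating, 4 fell and none rose (7 and 0 adjusted over the list alone), with a median of -0.63 log2. PakA (CCM_05107), a p21-activated kinase, fell by 1.26 log2 (SE 0.123, adjusted p = 0.00339) with VeA. The mating-type gene MAT1-1-1 (CCM_06523) had a log2 difference of -1.18 (SE 0.4, adjusted p = 0.0708), which did not pass. The camera adjusted p was 0.0293, and the adjusted p was 0.249 with an estimated correlation. With the length trend removed the median was -0.51 and the camera adjusted p 0.198, while VeA (-1.20, adjusted p = 0.00931) and PakA (-0.90, adjusted p = 0.00893) still passed.

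Zinc cluster transcription factors, a fungal family of regulators, fell at 30 and rose at 4 of 158 tested genes, the same counts adjusted over the list alone, with a median of -0.30 log2. CCM_08264 fell by 3.34 log2 (SE 0.316, adjusted p = 0.00339) and CCM_05638 fell by 2.60 log2 (SE 0.422, adjusted p = 0.00815), the latter from 2516 FPKM in passage 1 to 301.8 in passage 6. The camera adjusted p was 0.00681, and the adjusted p was 0.249 with an estimated correlation. These genes are long, with a median of 1.893 kb against 1.392 kb for all genes, and with the length trend removed the median was -0.17 and the camera adjusted p 0.385.

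The lists of ribosomal proteins, the mitochondrial ribosome, oxidative phosphorylation and the proteasome moved up by camera at its preset correlation, though fewer than 0.5 of the genes of each passed, none of the 4 passed with an estimated correlation, and each has a median gene length below that of all genes. Of 151 tested ribosomal protein genes, 52 rose and 7 fell (55 and 9 adjusted over the list alone), with a median of 0.40 log2. L12 (CCM_03950) rose by 1.33 log2 (adjusted p = 0.0148) and P2 (CCM_07272) by 1.52 log2 (adjusted p = 0.0214). The camera adjusted p was 7.33e-05, and the adjusted p was 0.249 with an estimated correlation. Of 14 genes of the mitochondrial ribosome 3 rose and none fell (4 and 0 adjusted over the list alone), with a median of 0.58, a camera adjusted p of 0.0239 and an adjusted p of 0.249 with an estimated correlation. CCM_00766 of this list rose by 0.97 log2 (adjusted p = 0.00878). Of 84 genes of oxidative phosphorylation 22 rose and 4 fell (28 and 7 adjusted over the list alone), with a median of 0.36, a camera adjusted p of 0.00681 and an adjusted p of 0.645 with an estimated correlation. COX23 (CCM_06842), an assembly factor of cytochrome oxidase, rose by 2.64 log2 (adjusted p = 0.0422). Of 38 proteasome genes 12 rose and 5 fell, the same counts adjusted over the list alone, with a median of 0.35, a camera adjusted p of 0.0148 and an adjusted p of 0.645 with an estimated correlation. The core subunits PRE3 (CCM_08753) and PUP3 (CCM_06966) both rose by 1.13 log2 (adjusted p = 0.00927 and 0.00866). Median gene lengths were 0.648 kb for ribosomal proteins, 0.597 kb for the mitochondrial ribosome, 0.592 kb for oxidative phosphorylation and 1.041 kb for the proteasome. With the length trend removed, the medians were 0.07, 0.10, 0.01 and 0.15 log2 and the camera adjusted p-values 0.972, 0.852, 0.959 and 0.385. The genes L12, P2 and COX23 no longer passed (adjusted p = 0.0591, 0.0828 and 0.101). Relative to all genes, the 7 lists named so far kept their sign under quantile scaling. TMM, median centring and FPKM differ by a constant per library, apart from the small value added before the log. Their like signs are therefore no separate check. With length removed, oxidative phosphorylation lay at -0.02 log2 against all genes. In that setting more of the called genes fell than rose among ribosomal proteins and in oxidative phosphorylation, opposite to the counts above. The mitochondrial ribosome and the proteasome kept their direction.

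**Figure D3:**
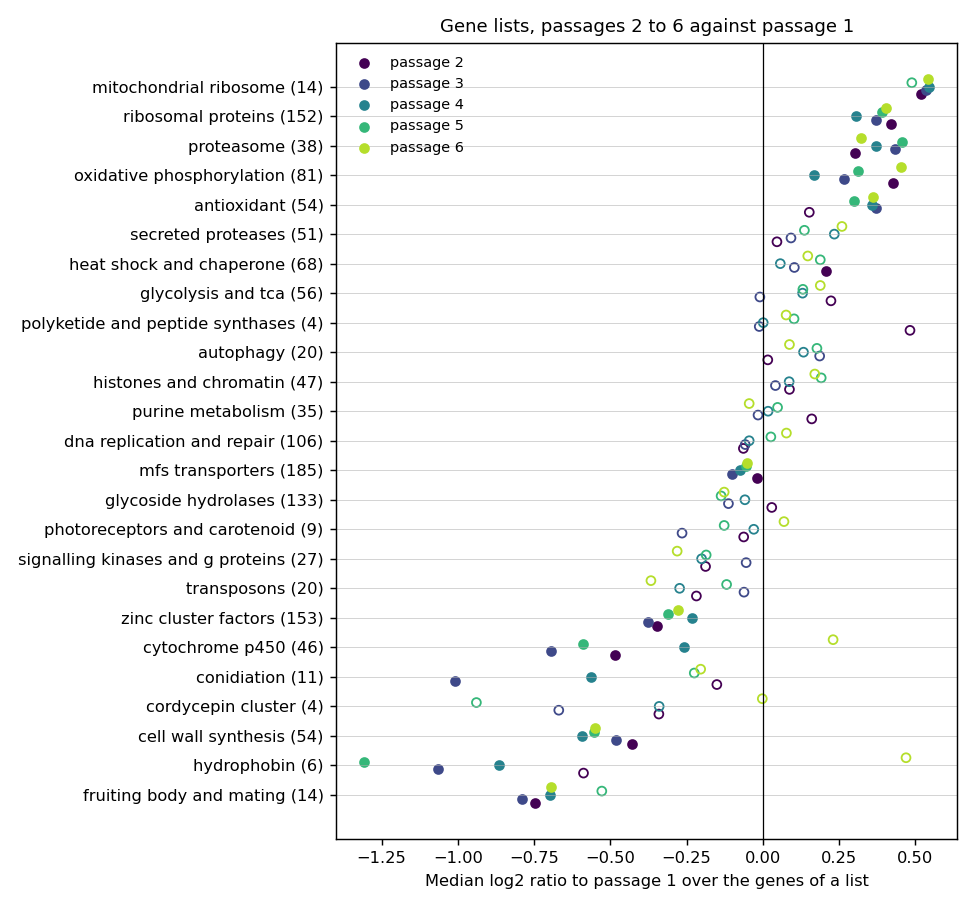
Points are the median log2 ratio to passage 1 over the genes of each list, in passages 2 to 6 (1 library each), with the number of genes in parentheses. Filled points lie outside the central 95% of 10000 random lists of equal size and like expression; ribosomal proteins lie between 0.31 and 0.42 and cell wall genes between -0.43 and -0.59.

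Of the 4 genes that make cordycepin and its protector pentostatin, only cns4 (CCM_04439), annotated as a transporter, passed in the comparison of passage 1 with the later passages. It fell by 0.72 log2 (SE 0.13, adjusted p = 0.0112), from 15.0 FPKM to between 10.1 and 11.6, and did not pass with the length trend removed (-0.18, adjusted p = 0.41). The synthesis gene cns1 (CCM_04436) had 237.9, 175.9, 68.0, 134.8, 73.3 and 250.5 FPKM in passages 1 to 6, a log2 difference of -1.0 (adjusted p = 0.276). Its partner cns2 (CCM_04437) was at 214.8 FPKM in passage 1, at 131.5 in passage 5 and at 551.2 in passage 6 (0.20, adjusted p = 0.857), and cns3 (CCM_04438) ranged from 29.1 to 65.9 FPKM (-0.19, adjusted p = 0.744). The FPKM given here are as deposited, with a median over genes 0.19 to 0.27 log2 above passage 1, while the log2 differences are TMM-scaled. They can disagree: in passage 6, cns1 was above passage 1 by FPKM but at 0.89 times passage 1 by TMM-scaled counts. The cluster as a list did not pass camera. Its median went from -0.453 to -0.077 log2 with the length trend removed, where 2 of its genes had a positive difference and 2 a negative one, against 1 and 3 before. In purine metabolism 6 of 35 genes fell and 4 rose (camera adjusted p = 0.975). Adenosine deaminase CCM_02911 fell by 1.49 log2 (SE 0.162, adjusted p = 0.00345) and a phosphoribosyl pyrophosphate synthetase (CCM_02500) fell by 0.85 (SE 0.196, adjusted p = 0.0232), both also with the length trend removed (adjusted p = 0.00799 and 0.0263).

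The remaining lists did not pass camera, though members did. By fry, which tests a list on its own, secreted proteases, heat shock genes, histones and transposons were called (medians 0.141, 0.174, 0.167 and -0.175 log2). So were the lists that passed camera. With the length trend removed, fry called only the cell wall and secreted protease lists. In that setting most called genes turned upward in DNA replication and repair (median 0.003 to 0.231 log2) and downward among antioxidant enzymes (0.278 to 0.005). Among 10 conidiation genes 4 fell and 1 rose (camera adjusted p = 0.215). Among those that fell were AbaA and Con-13 (CCM_00714), which fell by 2.98 log2 (SE 0.64, adjusted p = 0.0190). Of 6 hydrophobins, small proteins of aerial surfaces, 1 fell (camera adjusted p = 0.593), the trihydrophobin TCONS_00009105, at -2.24 log2 (SE 0.429, adjusted p = 0.0133). Secreted proteases rose at 9 and fell at 5 of 55 genes (camera adjusted p = 0.416), with the trypsin-like CCM_03489 up by 4.85 log2 (SE 1.37, adjusted p = 0.0422), an adjusted p of 0.0635 with length removed, and the subtilisin-like CCM_07318 up by 2.68 log2 (SE 0.706, adjusted p = 0.0346). Glycoside hydrolases rose at 12 and fell at 21 of 142 genes (camera adjusted p = 0.58), MFS transporters at 9 and 22 of 204 (0.732), and cytochromes P450 at 3 and 6 of 50 (0.392). Heat shock proteins and chaperones rose at 14 and fell at 10 of 69 genes (0.392), and antioxidant enzymes at 6 and 2 of 54 (0.195), among them thioredoxin CCM_07812, up by 2.10 log2 (SE 0.253, adjusted p = 0.00438). Signalling genes rose at 1 and fell at 6 of 27 (0.392), among the latter an RGS protein (CCM_03274) at -1.59 log2 and adenylate cyclase (CCM_06928) at -1.19 log2 (adjusted p = 0.00758 and 0.00438), the latter not passing with length removed (0.0571). For the others the genes that rose and fell numbered 5 and 9 of 56 in glycolysis and the tricarboxylic acid cycle (0.759), 4 and 12 of 106 in DNA replication and repair (0.593), 8 and 4 of 47 among histones and chromatin (0.556), 2 and 6 of 20 among transposons (0.416), 2 and 3 of 20 in autophagy (0.732), 1 and 1 of 6 polyketide and peptide synthases (0.85, with a median of 0.19 and a mean of -0.07) and none of 9 photoreceptor and carotenoid genes (0.759).

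A trend over passage number asks which genes move step by step with subculture. The smallest p among genes with a rising slope was that of a precursor of the acid protease endothiapepsin (CCM_07343), at 3.56 FPKM in passage 1 and 31.2 in passage 6, with a slope of 0.57 log2 per passage (SE 0.063, unadjusted p = 3.94e-05, adjusted p = 0.304). A methyltransferase (CCM_00251) went from 51.3 to 256.1 FPKM and had a slope of 0.33. On the falling side, the MFS transporter CCM_08259 had a slope of -1.94, from 29.4 to 0.11 FPKM, and a G protein-coupled receptor (CCM_05644) one of -0.72, from 116.4 to 11.3 FPKM. A xanthine, uracil and vitamin C permease (CCM_08692) went from 82.4 to 12.96 FPKM with a slope of -0.56. None of these passed. The fall of CCM_08259 lay mostly before passage 2, where it had 0.69 FPKM, and without passage 1 the slope of CCM_05644 was -0.444 and that of CCM_08692 was -0.364. No gene of 8758 passed in edgeR, with 1129 genes at an unadjusted p under 0.05. DESeq2 called 56 genes, 24 rising and 32 falling, with 1234 at an unadjusted p under 0.05, and limma on log2(FPKM + 1) called none, with 958. In camera, cell wall genes moved down with passage (adjusted p = 0.00293, or 0.65 with an estimated correlation), and ribosomal proteins (0.00293), oxidative phosphorylation (0.0255) and proteasome genes (0.0255) moved up, each at an adjusted p of 0.65 with an estimated correlation. Without passage 1 none of these lists passed, and the cytochrome P450 list alone did, upward (camera adjusted p = 0.0124). With the length trend removed, cell wall (downward) and DNA replication (upward) passed, both at a camera adjusted p of 0.00129, but not at adjusted p = 0.91 and 0.682 with an estimated correlation.

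The authors' deposited table of genes apart from passage 1 listed 1892 genes in passage 2 (1253 higher, 639 lower), 2498 in passage 3 (1729 and 769), 2006 in passage 4 (1511 and 495), 2273 in passage 5 (1437 and 836) and 2188 in passage 6 (1602 and 586). Of 3818 genes in any of the authors' 5 lists, 855 were in all 5, of which 609 were higher and 242 lower in every one. Among the 8483 genes with a mean of at least 1 FPKM, the lists of passages 2 and 3 held 1188 and 1639 higher genes and shared 978, where independent lists would share 229.5, and they held 606 and 726 lower genes and shared 487, against 51.9. All 5 lists share the passage 1 library, so independent lists are not the full comparison. By size alone, with TMM-scaled counts and 0.1 CPM added (another offset than for the 807 genes apart in passage 1), 391 genes were at least 2-fold higher and 415 at least 2-fold lower in all 5 later passages. With the libraries shuffled within each gene, which keeps a shared control, 100 shuffles gave means of 79.9 higher and 84.6 lower genes, and at most 104 of either. Each gene was shuffled separately, so the means spread the genes apart in any 1 library evenly over the libraries. A difference of the passage 1 library as a whole, such as its trend with gene length, would exceed these numbers as well.

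Sequence variants against the CM01 reference were counted to see whether the strain's sequence changed with passage. The authors' table held 134783 sites, of which 126923 were single nucleotide sites, 4033 insertions and 3827 deletions. Exons held 79173 of them, introns 9345 and intergenic sequence 10267, with 56771 synonymous, 21469 nonsynonymous and 116 stop-gain changes. Genes with the most exonic sites were a nonribosomal siderophore peptide synthase (CCM_01705, 121 sites) and the adenylation domain genes CCM_01285 (117) and CCM_03255 (116). Passages 1 to 6 carried 101501, 111757, 109520, 114065, 111915 and 110952 sites, and 86300 (64.0%) were common to all 6. Of 61937 sites with at least 10 reads in every library, 59134 (95.5%) were common to all. The number of sites per library correlated with total counts (r = 0.819, exact permutation p = 0.0292, adjusted 0.0889, and rho = 0.543, p = 0.2972). With passage, r was 0.636 (exact permutation p = 0.1639) and rho 0.486 (p = 0.3556). Without the 2 libraries farthest from the median of total counts, r with total counts was -0.381, so it rests on those libraries. Without the 2 farthest from the median passage number, r with passage was 0.349. Of 43268 sites with a single allele in each library, 42986 held the same allele in all 6, and 24 to 33 per library differed in that library alone.

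Calls with both alleles at a site made up 0.970% of calls in passage 1 (95% Wilson interval 0.913 to 1.03%) and 2.82% to 4.02% in passages 2 to 6. Of these calls, 19.11% in passage 1 and 68.1% to 76.79% in passages 2 to 6 lay in 3 stretches of the genome, and 821 in passage 1 and 1009 to 1217 per later passage lay elsewhere. The stretches were defined after the calls had been seen: scaffold NW_006271973.1 from 69686 to 598030, NW_006271974.1 from 1187874 to 1597917 and NW_006271975.1 from 1324052 to 2098011. These held 94.8% of 1674 sites that had at least 20 reads in every library and both alleles in at least 4 libraries, and 7.59% of 45803 single nucleotide sites covered as well. Exonic sites lay in 153, 103 and 241 genes of the 3 stretches. At the 1561 of 1587 such sites in the stretches where passage 1 had a single allele (26 were left out), the other allele had a median share of reads of 0% in passage 1, 30.43% in passage 2, 9.13% in passage 3, 64.29% in passage 4, 41.86% in passage 5 and 73.97% in passage 6. Pooled over reads, the shares were 0.453% (Wilson interval 0.425 to 0.482), 32.7%, 9.78%, 65.3%, 43.8% and 74.4%. As a background, reads of the reference allele made up 0.0768% to 0.106% at 41726 sites elsewhere. Those sites were coded for the alternative allele alone in all 6 libraries, a stricter choice than that of the sites in the stretches. The share correlated with passage (r = 0.835, exact permutation p = 0.0417, adjusted 0.0889; rho = 0.886, p = 0.0333), and r was 0.502 without the 2 farthest libraries.

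**Figure D4:**
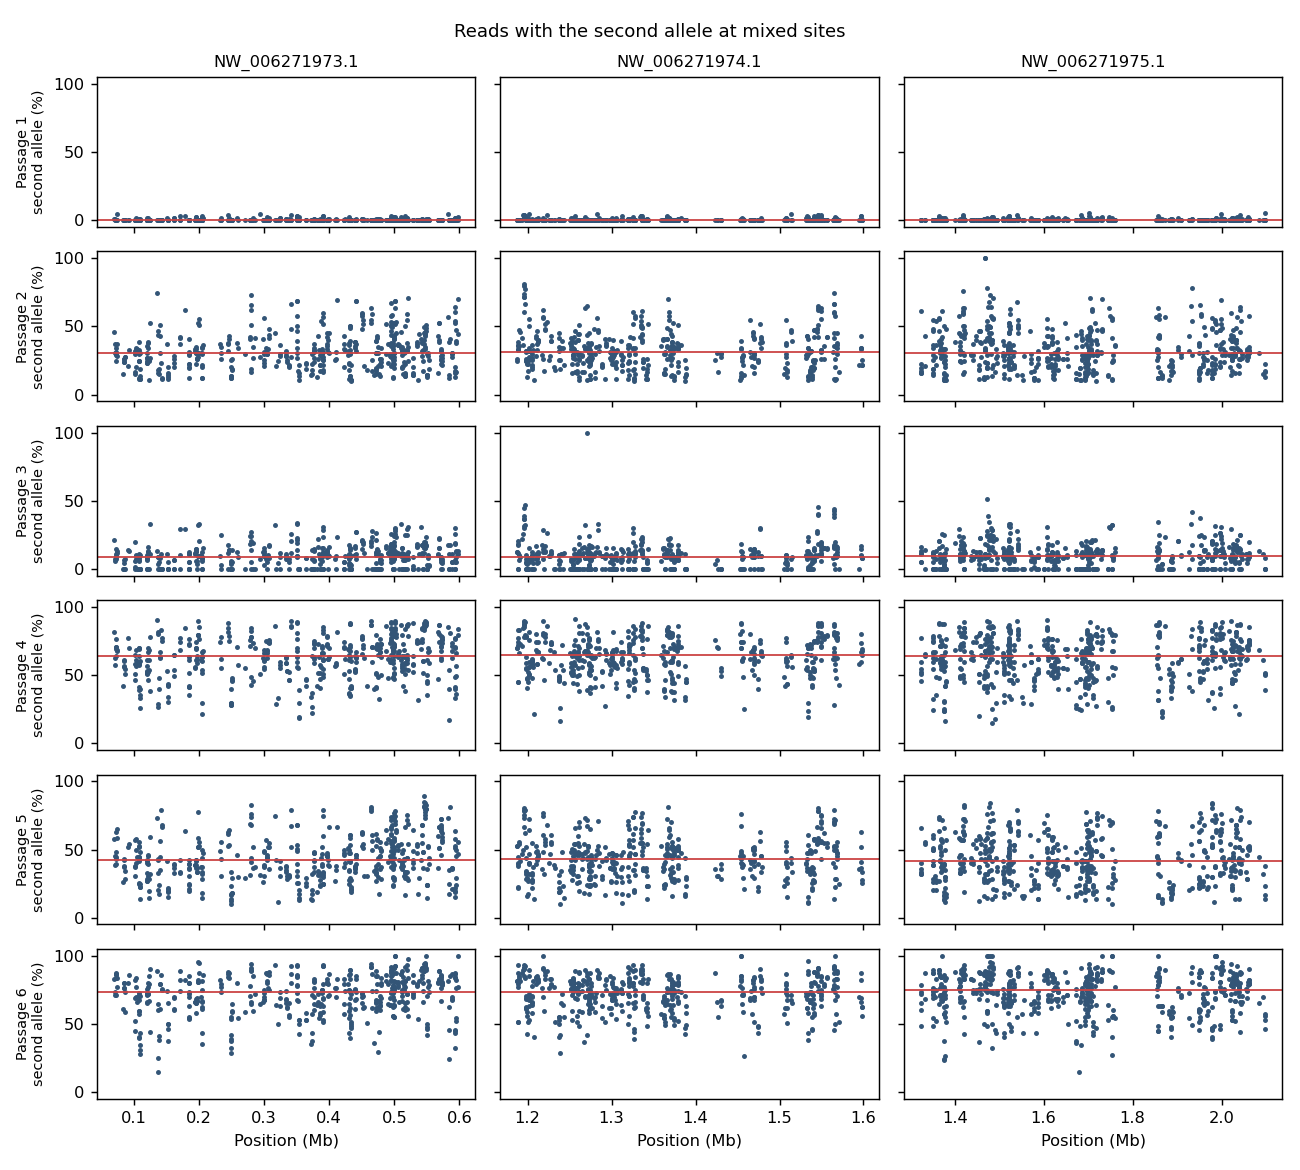
Points are the percent of reads with the allele that passage 1 lacked, at mixed sites along 3 scaffolds (columns, position in Mb) in passages 1 to 6 (rows of panels, 1 library each); red lines are medians of a stretch. Over the 3 stretches the median is 0 in passage 1, 9.13% in passage 3 and 73.97% in passage 6.

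The mating-type gene MAT1-1-1 lies in the stretch on NW_006271973.1. Its expression was 10.5, 5.46, 6.58, 3.01, 4.66 and 3.51 CPM in passages 1 to 6. Over the 6 libraries it correlated with the share of the second allele at r = -0.901 (exact permutation p = 0.0056, adjusted 0.0278) and rho = -0.943 (p = 0.0167, adjusted 0.0833), and r was -0.996 without the 2 farthest libraries. With passage, r was -0.805 (exact permutation p = 0.0444, adjusted 0.0889) and rho -0.771 (p = 0.1028). At its exonic variant site at 417379, all 9 to 26 reads per library had the allele of passage 1. Its other 3 sites had 0 to 7 reads per library, too few to exclude another allele, and 1 of these reads, the only read at 417610 in passage 5, had the other allele. Mixed sites lay 5.8 kb to one side in the Sla2 gene CCM_06521 and 4.6 kb to the other in the DNA lyase gene CCM_06524. These correlations belong to a family of 10 relations, which does not cover the choice of this gene after the values were seen. Of 450 tested genes in the stretches, 82 had an unadjusted p under 0.05 against the same share in edgeR.

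RNA editing events in the authors' table numbered 208 in passage 1, 2511 in passage 2, 1401 in passage 3, 2481 in passage 4, 2473 in passage 5 and 2230 in passage 6. They lay at 3486 positions, and the genes with the most such positions were an ankyrin repeat gene (CCM_06520, 40 positions), a cytidine deaminase-like gene (CCM_06584, 39) and a topoisomerase II-associated gene (CCM_06557, 37). In passages 2 to 6, 90.12% of 11096 events lay in the 3 stretches with mixed alleles, and the events elsewhere numbered 154, 228, 168, 230, 213 and 257 in passages 1 to 6. Each of the 11304 listed frequencies equalled the share of reads in the variant table within 0.005, and 92.8% to 99.5% of a library's events were at mixed calls. By their deposited title the events were based on single nucleotide variants. This match may therefore follow from how they were called, and is no separate evidence. Nonsynonymous events numbered 83 in passage 1 and 373 to 664 in passages 2 to 6. Events correlated with passage at r = 0.642 (exact permutation p = 0.1944) and rho = 0.2 (p = 0.7139).

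**Figure D5:**
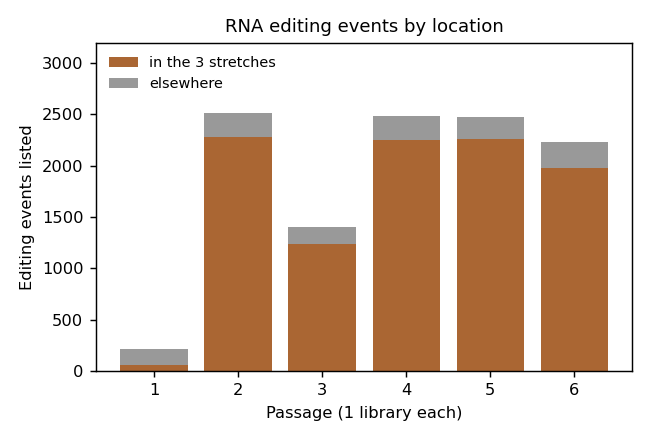
Bars are RNA editing events listed in each passage (1 library each, no error), divided into events in the 3 stretches with mixed alleles and events elsewhere. Passage 1 has 208 events, of which 54 are in the stretches, and passage 2 has 2511, of which 2283 are there.

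Splice junctions were compared to see whether splicing changed with passage. Alternative junctions were most numerous in glyceraldehyde 3-phosphate dehydrogenase (CCM_04549, 65), the splicing factor gene prp4 (CCM_00694, 51) and the WD repeat gene CCM_04398 (51). Passages 1 to 6 had 2438, 3040, 2725, 2964, 2857 and 3101 of them, or 16.3%, 18.3%, 17.1%, 17.8%, 17.6% and 18.5% of all junctions, and they held 13.38% to 13.76% of junction reads. Wilson intervals were 15.7 to 16.9% in passage 1 and 17.9 to 19.1% in passage 6. Their number correlated with total counts at r = 0.982 (exact permutation p = 0.0028, adjusted 0.0278) and rho = 0.943 (p = 0.0167, adjusted 0.0833), and r was 0.934 without the 2 farthest libraries. With passage, r was 0.659 (exact permutation p = 0.1444) and rho 0.6 (p = 0.2417). The authors' tables also listed 734 genes outside the reference annotation, 519 of them with a mean of at least 1 FPKM, and 3695 extended gene models, 2010 at the 5′ end by a median of 273 bp and 1727 at the 3′ end by a median of 230 bp.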

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

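The thinning test of depth and the correlation with gene length were chosen after passage 1 had been seen to stand apart but before their own results were seen, other orders of the libraries were chosen beforehand, and the tests with the length trend removed and all tests of mixed alleles and editing events were chosen only after the result was seen.

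A second allele appeared in 3 stretches of the genome in variant read numbers outside the expression comparisons, where passage 1 had a median share of 0% (0.453% of pooled reads, interval 0.425 to 0.482, at sites kept for a single allele there, and 0.0768% at background sites): 30.43% of reads in passage 2, 9.13% in passage 3, 64.29% in passage 4, 41.86% in passage 5 and 73.97% in passage 6. Reads of near-identical gene copies placed together would be mixed in passage 1 as well, but of 1582 sites in the stretches chosen as mixed in at least 4 of passages 2 to 6, without regard to passage 1, only 3 (0.19%) were mixed there, and reads from an unrelated strain would spread over all scaffolds, while the stretches held 94.8% of sites mixed in at least 4 libraries and, of all mixed calls, 68.1% to 76.79% in passages 2 to 6. Within each library the median shares of the 3 stretches, on separate scaffolds, differed by at most 1.67 percentage points, but a group of 23 mixed sites outside them, left out by a minimum of 100 sites set after it was seen, had 24.39% in passage 4 and 40.71% in passage 6, well below the stretches. The 3 stretches are consistent with a second, related genotype that made up a varying part of the mycelium of passages 2 to 6, while that group and the 1009 to 1217 mixed calls elsewhere in each of these passages stay unexplained. Whether this genotype was present in the culture or entered during handling of the cultures or libraries cannot be separated with 1 library per passage. The pooled reads of passage 1 above background leave a small share there open, though the background sites were chosen more strictly. So do its 1015 mixed calls, counted at any depth, of which 19.11% lay in the stretches. Of single nucleotide sites with at least 20 reads in every library, 7.59% lay there. No biological explanation beyond the passage itself was tested.

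The authors' editing events numbered 208 in passage 1 and 1401 to 2511 in the later passages, and 90.12% of the events of passages 2 to 6 lay in the same 3 stretches. Deamination of the RNA would have no reason to keep to these stretches, which held 82.82% of edited positions and 8.39% of exonic single nucleotide sites. Read on the coding strand, changes from A to G were 0.745 times as frequent as the reverse (1.002 times at variant sites). Changes from C to T were 1.443 times as frequent as the reverse (0.984 times at variant sites), too near the bound of 1.5 set for that test to decide. Both ratios also depend on which genotype carries the reference base. A to G held 421 positions and T to C, its form on the other strand, 594, which argues against adenosine deamination as the main source. C to T was 1.517 times as frequent as G to A, little above 1.407 times at variant sites, so little excess of C to T on the coding strand was left. A candidate explanation for most events is that mixed genomic alleles were listed as editing. It stays open as the whole explanation, since the number of events elsewhere ranged from 154 to 257, more than the 1.5-fold set for that test, and correlated with the number of all events, which includes them (r = 0.851, exact permutation p = 0.0278, adjusted over 3 relations 0.0306; rho = 0.6, p = 0.2417; r = -0.873 without the 2 farthest libraries, so it rests on those), and with total counts (r = 0.952, p = 0.0056, adjusted 0.0167; rho = 0.829, p = 0.0583; 0.672 without the 2 farthest).

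The passage 1 library stood apart in expression, with 807 genes at least 2-fold from every other library. Lower depth of this library is argued against by 790 such genes with all libraries thinned to the smallest, against at most 90 in another library. A gene length bias was present to the degree set as its mark (rho = -0.389 between length and the change after passage 1); with it removed, 627 genes were apart, against at most 71 in another library, which argues against length as the whole cause, and the cell wall list had an adjusted p of 0.0116 (0.959 with an estimated correlation). Of the other lists 0 of 6 were still called: length bias may account for ribosomal proteins, whose median went from 0.40 log2 (quartiles -0.05 to 0.73) to 0.07 (-0.36 to 0.43), for the mitochondrial ribosome (0.58 to 0.10) and for oxidative phosphorylation (0.36 to 0.01), but the proteasome (0.35 to 0.15), zinc cluster (-0.30 to -0.17) and fruiting and mating lists (-0.63, quartiles -1.17 to -0.08, to -0.51, quartiles -0.88 to 0.02) moved less and stay open. For the trend, the real order called 0 genes, so 100 of 100 orders had to call as many. The count therefore says nothing about chance, but the highest other order called 101, which points to a structure of the samples. A change with subculture and an unrecorded difference in the handling of passage 1 both stay open, the first untested. The second allele of the 3 stretches, at a median share of 0% in passage 1, also sets this library apart. Whether the mix of genotypes bears on expression outside the stretches was not tested and cannot be separated from the passage.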

How the results depend on the processing

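The settings with gene length, thinning, FPKM as deposited, limma on log2(FPKM + 1), edgeR without an expression filter, the 5 later passages together and editing events outside the stretches were chosen only after the data were seen. Of 145 alternative values for counts and correlations, 119 stayed (counts within 1.5 times, whatever their directions), and 26 moved. Of 228 for named genes 198 stayed and 30 moved, 27 of them with quantile normalization and 3 with a prior count of 5. The 1.5 times was not the measure for named genes, and those that stayed were not always close. CCM_00410 in passage 3 stayed at a log2 ratio of 9.81 with a prior count of 0.1, against 6.50. CCM_07919 in passage 4 moved at -4.58 with quantile normalization, against -4.90. None of the 228 values reversed in sign. They cover genes named for single passages and for the trend, and not the members of lists or the comparison with the later passages together. The more frequent direction among genes at least 2-fold from passage 1 did turn: 43.0% to 54.0% were higher over the scalings, filters and prior counts on counts, and 61.9% to 73.5% with FPKM as deposited. Against the later passages together, 70.4% were higher in limma on log2(FPKM + 1) and 33.6% to 42.9% in the other settings. At a 4-fold minimum the genes apart from passage 1 numbered 327, 497, 250, 430 and 282 in passages 2 to 6, and those of the authors' lists 428, 639, 394, 548 and 452, fewer by construction. Against the preceding passage, passages 3 to 6 had 402, 456, 382 and 792. The trend gave 56 genes in DESeq2 and 0 in edgeR, and the cause was not tested. The 4 gene lists with a trend became 0 with an estimated correlation and 0 in fry, and 1 to 4 with a passage left out, the lowest without passage 1; the cause was not tested. Passage 1 against the later passages gave 1380 to 2534 genes with a later passage left out, the lowest without passage 5. The 7 lists called there at the preset correlation were called with each later passage left out, but none passed with an estimated correlation. With the length trend removed only the cell wall list passed. Sites in passage 1 numbered 66575 with at least 10 reads, since fewer sites have them. Editing events outside the stretches were 228, 168, 230, 213 and 257 in passages 2 to 6. The lowest correlation of passage 1 was 0.862 with untransformed FPKM. No paired analysis was possible because each passage has 1 library. The simulation for the comparison of passage 1 with the later passages took its spread from the trend fit, so it does not give the power of that comparison. That for the trend drew libraries independently, so it does not give the power of the trend test on neighbouring passages.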

Other observations

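The genes and gene families in the first 2 paragraphs and the tests of MAT1-1-1 and of expression in the stretches were chosen only after the result was seen.

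Of 6 neighbouring genes picked for their values, 5 passed as lower after passage 1, with no test of neighbouring genes as such. Beside the MFS transporter CCM_08259, which fell by 6.62 log2 (SE 0.452, adjusted p = 0.00319, edgeR), the transcription factor CCM_08260 fell by 1.96 log2 (SE 0.208, adjusted p = 0.00345), DmbB (CCM_08262, at 3.99 FPKM in passage 1) fell by 5.18 log2 (adjusted p = 0.00857), the cytochrome P450 CCM_08263 fell by 3.81 log2 (adjusted p = 0.00645) and the zinc cluster factor CCM_08264 fell by 3.34 log2 (adjusted p = 0.00339). DmbS (CCM_08261), which lies among them, did not pass (-0.81, adjusted p = 0.0578). Chitin synthases, the enzymes that make wall chitin, fell at 7 of 11 tested genes and rose at none, with a median of -1.01 log2. CCM_02966 fell by 1.96 log2 (adjusted p = 0.00345) and chitin synthase 6 (CCM_02965) fell by 1.89 log2 (adjusted p = 0.00319). These genes are long, with a median of 2.769 kb, and with the length trend removed 4 fell, with a median of -0.68 log2.

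Other neighbouring genes differed between later passages. The galactomannoprotein CCM_00404 had 44.8, 379.2, 719.7, 166.9, 157.9 and 119.1 FPKM in passages 1 to 6, with its highest value in passage 3, where CCM_00403, CCM_00410 and CCM_00411 also had theirs. The ubiquitin ligase gene Hul4 (CCM_00412) and the fatty acid hydroxylase CCM_00413 had like profiles, at 59.7, 0.1, 0.63, 90.2, 6.48 and 19.2 FPKM and at 64.8, 1.43, 1.12, 61.1, 5.75 and 17.8 FPKM. With 1 library per passage these values have no test. A group of 23 mixed sites on scaffold NW_006271975.1, from 2555204 to 2594677, had second allele shares of 0.22%, 22.2%, 6.72%, 24.4%, 25.4% and 40.7% in passages 1 to 6.

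A hypothesis is that the second genotype of the 3 stretches lacks MAT1-1-1, as a strain of the other mating type would. MAT1-1-1 CPM fell with the share of the second allele (r = -0.901 over 6 libraries, exact permutation p = 0.0056), which is consistent with it. At 417379 in the gene all 9 to 26 reads per library had 1 allele, while sites 5.8 kb and 4.6 kb away were mixed; its other 3 sites had 0 to 7 reads and decide little, though the only read at 417610 in passage 5 had the other allele, which goes against the hypothesis. Divided by the median share of the first allele over the 3 stretches, expression was 10.5, 7.85, 7.24, 8.42, 8.01 and 13.5 CPM in passages 1 to 6. These values are rough, since the nearest mixed sites had other shares of the second allele. In passage 2 the shares were 69.3% and 37.3%, against a median of 30.43%, and in passage 3 they were 23.7% and 5.4%, against 9.13%. Of 450 tested genes in the stretches, 82 had an unadjusted p under 0.05 against the share in edgeR. A relation to the share is therefore not particular to MAT1-1-1. A fall of expression of the gene in a single genotype stays open, and sequence of the other mating-type gene was not analysed here.

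A further hypothesis is that the mix of genotypes sets expression of genes in the stretches. Against the share of the second allele, edgeR called 1 of 8758 genes, with 798 at an unadjusted p under 0.05, and 82 of these lay in the stretches. The unadjusted p was taken up after this single call had been seen. Of the 798 genes 10.3% lay in the stretches, against 4.62% of the other genes, a ratio of 2.223. In 13 of 100 orders of the libraries that ratio was as high, up to 4.45, so the hypothesis stays undecided. Without passage 1 edgeR called 22 genes, and 4 of them lay in the stretches (18.2%, against 5.11% of genes not called, Fisher's exact p = 0.0241); genes are not independent, and other orders were not run for this fit. Reads of the second allele may also align less well than those of the first, which was not tested.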
